A study of Homo sapiens with 40 samples.

How the data were processed

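Omni-ATAC-seq libraries of primary human fibroblasts (HFF, 34 libraries) and of the lung adenocarcinoma line A549 (6 libraries) were analysed from the files the authors deposited. Per the labels' protocols, libraries were sequenced as 50 bp single-end reads; the labels also gave the stiffness, compound, dose, time and replicate of each library. Per the labels' protocols, more cells of both types were seeded on softer gels, for fibroblasts because fewer attach there, and nuclei were released on the dish without trypsin, so cell density at harvest can differ between gels. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.32, Bowtie (version 1.0 in part of the notes), Picard, bedtools 2.25, MACS2, featureCounts, DESeq2, ChIPseeker and deepTools 3.0.1, with the genome build hg38. The order and options of these steps, the peak threshold and any shift of reads for the Tn5 cut are not given in the sources used here.

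For each library the authors deposited a MACS2 list of peaks, so peaks were called per library and not on pooled samples. Per the file headers and layout, a peak has a fold enrichment (a ratio), a −log10 p-value and a −log10 q-value, which are the authors' own values; they were used only to rank and filter peaks within a list. No list gives the number of reads, so the depth behind a peak is unknown for most libraries, and a library with more reads has more and weaker peaks. Lists were therefore compared over the 50000 peaks with the highest −log10 p in each library. A peak sat in a region when they shared at least 1 bp.

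The authors also deposited 2 tables made with HOMER over the same 224906 merged regions, 1 for 50 against 1 kPa and 1 for 50 kPa against 50 kPa with Y-27632. Per the file headers, the Y-27632 table came from a DESeq2 comparison with variance-stabilised values; the stiffness table has the same columns. Each table has log2 values per library (the authors' variance-stabilising transform), a log2 fold change, a p-value and an adjusted p-value from the authors. The unit assumed beforehand was counts, and log2 values were found, so the authors' adjusted p-values were counted by direction in place of a count test. The transform was inverted, and 100% of regions came out within 0.05 of a whole tag in every library; these recovered tags, divided by size factors over the 8 libraries, give the normalised tags in the text. The 8 libraries had 30351878 to 64424710 tags in the headers, with 22290047 to 44402944 in regions, so regions with few tags have less precise fold changes. The column names carry no set name: the 1 kPa and Y-27632 columns were matched to BDC4 by name, the 50 kPa columns would also match BDC3, and no column could be tied to a single library. Regions outside the autosomes and X (517) were left out, leaving 224389. Coordinates are hg38 as in the tables, and gene names and annotation classes (intron, exon, TTS, promoter) come from the tables. Leading regions of a comparison are named by the nearest protein-coding TSS. For the study's genes and the gene lists, any region within 50 kb of a member's TSS was taken, even where another TSS was nearer. A region could thus count for several genes or lists. The gene given need not be the gene that the region regulates. Entrez gene IDs matched the reference table for 223104 regions.

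Libraries were compared over BDC3, BDC4, the inhibitor set and A549 as the labels group them. The peak presence test was an exact conditional test per region over 17 untreated or DMSO fibroblast libraries, two-sided, with libraries exchanged only within BDC3, BDC4 or the inhibitor set, over regions present in at least 2 and absent from at least 2 libraries, with Benjamini-Hochberg adjustment. The stiffness index was compared by exact permutation tests, two-sided, adjusted over 9 contrasts. Regions with a peak in every library of 1 group and none of the other were counted and set against all 10 splits of 6 libraries, since 3 against 3 libraries cannot reach an adjusted p of 0.05 per region. Similarity was the Jaccard index of bases under peaks. Differences of differences between cell types or compounds were tested by permuting cell type or compound labels within each gel, two-sided, also with each group centred on its mean over both gels.

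There were 19 gene lists, fixed together with the main tests and alternatives before the data were examined: genes named by the study (9), YAP/TAZ targets (22), MRTF/SRF and actin (25), AP-1 and immediate early (13), matrix and fibrosis (25), focal adhesion and integrin (23), nuclear envelope (12), cell cycle (22), inflammatory and NF-kB (18), sterol and lipid (12), BCL2 family (14), Wnt (16), and markers of fibroblasts (12), epithelium (12), keratinocytes and melanocytes (8), endothelium (8), immune cells (8) and neurons (8). Of these, 1 list is not named and, with 1 gene of another list, not reported here. Regions within 50 kb of a member's TSS were tested by Fisher's exact test against other regions near a protein-coding TSS, adjusted over lists. Neighbouring regions move together, so a comparison with 10000 random lists matched on regions per gene was added after seeing the data. On 200 random lists Fisher's exact test gave p under 0.05 for 15.5% (higher) and 19.5% (lower), and the matched comparison for 4.5% and 6.0%. Markers were read as peaks within 1 kb of a TSS. The text names the 9 genes of the study's description by their region with the smallest adjusted p within 50 kb. Up to 4 members per list, those with the smallest such p, are named in the same way. Per comparison with calls, it names the 10 regions per direction with the smallest adjusted p, by the nearest protein-coding TSS within 100 kb. Without calls, it names 5 regions per direction ranked by summed −log10 p. Y-linked genes were left out.

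Alternatives covered all deposited peaks, the 25000 strongest peaks, peaks with −log10 q of at least 5, adjusted p of 0.01, log2 fold changes of at least 1, at least 10 tags, 10 kb or the nearest TSS for gene lists, libraries left out in turn, sets left out and a replicate block. Fits with limma on the variance-stabilised values and limma-voom on the recovered tags, with other scalings, were added after the data were seen. In simulated data with 200 of 187596 regions changed by a factor of 2, limma-voom recovered 45.5% of them (95.4% of those with a mean of at least 120 tags), with 13.3% false among 105 calls; with 40000 changed regions it recovered 70.9%, with 3.47% false. The presence test recovered 99.0% of 8000 changed regions among 40000, with 1.17% false. These changed regions were simulated with peaks in nearly all libraries of 1 gel and nearly none of the other, alike in every set. The recovery therefore says nothing about weaker changes or changes that differ between sets. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. Motif content was not analysed here.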

Results

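Chromatin accessibility was measured by Omni-ATAC-seq, in which the Tn5 transposase places sequencing adapters into open DNA, in 40 libraries of cells grown on hydrogels of defined stiffness. Primary human fibroblasts (HFF) gave 34 libraries, and A549, a human lung adenocarcinoma line, gave 6. Cells had 20 h on gels of 1 kPa (soft), 12 kPa or 50 kPa (stiff). The fibroblast set BDC3 held 2 libraries at 1 kPa and 3 at 50 kPa. The set BDC4 held 3 libraries at each of 1, 12 and 50 kPa and 3 at 50 kPa with Y-27632, an inhibitor of the kinases ROCK1 and ROCK2, at 10 µM for 1 h. Of these, 1 library at 50 kPa without inhibitor and 2 with Y-27632 carry the mark B2 in their names. They count with BDC4 below, except where Y-27632 is also compared within each library series. In the inhibitor set, fibroblasts at 1 and 50 kPa were given DMSO (3 and 3 libraries) or CCG-222740, an inhibitor of transcription driven by MRTF, at 20 µM for 18 h (2 and 3). Others were given verteporfin, which blocks the binding of YAP to TEAD factors, at 0.7 µM for 18 h (3 and 3). A549 cells had 3 libraries at each of 1 and 50 kPa.

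Every library had its own list of peaks, from 78462 peaks (replicate 1 of CCG-222740 at 50 kPa) to 172280 (replicate 1 of BDC3 at 1 kPa). A pair of tables by the authors also held tag values over 224906 merged regions (hg38, median length 455 bp) for 3 libraries at 1 kPa, 2 at 50 kPa and 3 at 50 kPa with Y-27632. These 8 libraries had 30351878 to 64424710 tags, of which 22290047 to 44402944 lay in the regions. The depth of the other libraries is unknown. More cells of both types were seeded on softer gels, so stiffness and seeding number changed together. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

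The comparison of 1 and 50 kPa asked which regulatory regions of fibroblasts differ in accessibility between a soft and a stiff substrate. On the stiff gel, regions were more accessible near targets of YAP and TAZ, the coactivators controlled by the Hippo pathway, and near actin cytoskeleton genes driven by MRTF and SRF. Near MYH9, which encodes the heavy chain of non-muscle myosin IIA, normalised tags went from 217 ± 12.2 (SD, n = 3) at 1 kPa to 702 ± 11 (SD, n = 2) at 50 kPa. Near RASL12, a gene of the Ras-like family, and MMP14, which encodes a membrane-bound matrix metalloproteinase, accessibility was lower on the stiff gel. In the authors' deposited table, 39495 of 224389 regions were more accessible at 50 kPa and 38652 less accessible at their adjusted p of 0.05. Of the more accessible regions, 49.7% lay in introns, 38.4% between genes and 5.87% at promoters, and of the less accessible ones 48.5%, 43.2% and 3.56%. Within 1 kb of a transcription start site (TSS) lay 9.17% of the more accessible regions, 6.00% of the less accessible ones and 9.65% of those without a call.

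The study's description names 9 genes, and each was represented by the region within 50 kb of its TSS with the smallest adjusted p. These genes were picked by the study on its own data, so their directions are not independent evidence. CCN1 and CCN2 encode secreted matricellular proteins and are targets of YAP. The region at CCN1, in its last exon (chromosome 1, 85582346 to 85583317), went from 170 ± 7.35 to 973 ± 8.67 tags. That at the 3' end of CCN2 (chromosome 6, 131946938 to 131947559) went from 32.4 ± 1.78 to 192 ± 44.5. An intronic region of SKP2, which encodes an F-box protein that drives cell cycle entry (chromosome 5, 36156183 to 36157221), went from 58.3 ± 8.87 to 664 ± 12.4 tags. An intronic region of NF2, which encodes the Hippo pathway regulator merlin (chromosome 22, 29621676 to 29622601), went from 204 ± 17.1 to 774 ± 27 tags. An intronic region of RANGAP1, which encodes a GTPase-activating protein of nuclear transport (chromosome 22, 41290499 to 41291212), went from 108 ± 3.05 to 545 ± 54.9 tags. The intronic MYH9 region lay at 36368366 to 36369230 of chromosome 22. An intergenic region near FZD2, which encodes a Wnt receptor (chromosome 17, 44543061 to 44544278), went from 513 ± 25.5 to 2326 ± 296 tags. An exonic region assigned to RFLNB, which encodes a filamin-binding protein (chromosome 17, 409768 to 411376), went from 297 ± 19.7 to 537 ± 36.5. Only the intronic region of BMF, a pro-apoptotic member of the BCL2 family (chromosome 15, 40092306 to 40093569), was lower on the stiff gel among these 9. It had 736 ± 12.3 tags at 1 kPa and 114 ± 5.42 at 50 kPa. The authors' deposited table gave log2 fold changes (50 over 1 kPa) of 3.53 for SKP2, 2.58 for CCN2, 2.53 for CCN1, 2.34 for RANGAP1, 2.19 for FZD2, 1.94 for NF2, 1.71 for MYH9, 0.86 for RFLNB and −2.68 for BMF. Adjusted p in the authors' deposited table ran from 4.57e-121 (FZD2) to 1.46e-11 (RFLNB). The plot of tags by gene shows the single libraries.

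**Figure D1:**
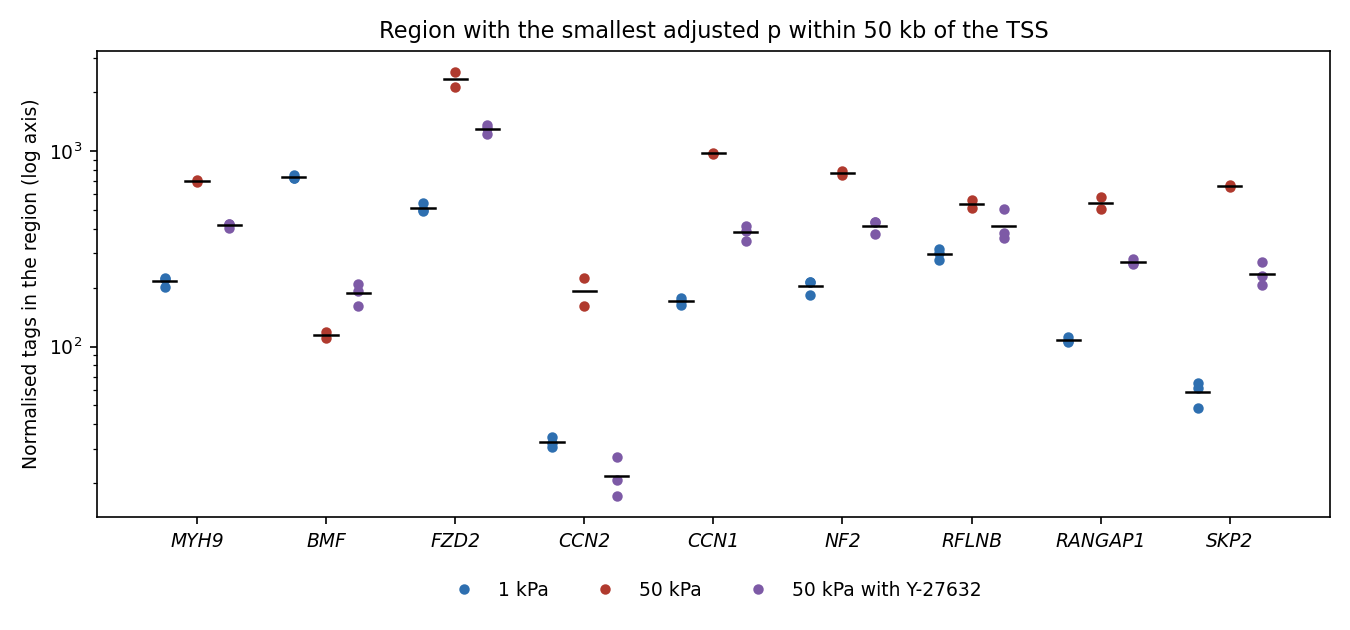
Normalised tags (log axis) in the region with the smallest adjusted p within 50 kb of the TSS of 9 genes, at 1 kPa (blue, n = 3), 50 kPa (red, n = 2) and 50 kPa with Y-27632 (purple, n = 3); each point is 1 library and each bar a group mean. At 50 kPa both libraries lie above all 3 at 1 kPa for 8 genes and below them for BMF, and the Y-27632 means lie between both other means except for CCN2, where the Y-27632 mean of 21.8 tags is under the 32.4 at 1 kPa.

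The 10 regions per direction with the smallest adjusted p were all annotated outside promoters. An intergenic region near SUDS3, a subunit of a histone deacetylase complex (chromosome 12, 118436164 to 118437553), went from 66.3 ± 9.65 tags at 1 kPa to 1162 ± 15.4 at 50 kPa. An intron of RAD18, a ubiquitin ligase of DNA damage tolerance (chromosome 3, 8887651 to 8888763), went from 97.9 ± 14.4 to 1259 ± 82.2 tags. Others among the 10 leading regions lay near TSEN15, FAM107A, PPP2R3A, EBNA1BP2, FZD2, BCL10 and DCLK1. A further one lay near both ENTPD4 and LOXL2, which encodes a collagen cross-linking enzyme. In the authors' deposited table, these had log2 fold changes between 2.04 (BCL10) and 4.14 (SUDS3). On the soft gel the leading region lay near RASL12 (chromosome 15, 65068908 to 65069840), with 992 ± 18.1 tags at 1 kPa and 103 ± 9.04 at 50 kPa. The intergenic region near MMP14 (chromosome 14, 22847791 to 22849900) went from 1998 ± 76.0 to 710 ± 99.7 tags. The other regions lower at 50 kPa lay near ANGPTL2, BMF, KLF13, COPS8, TSPAN11, CCDC28A, PRCD and CAPS, with log2 fold changes in the authors' deposited table from −3.12 (COPS8) to −1.57 (PRCD).

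Grouped by gene lists set before the data were examined, YAP/TAZ targets and MRTF/SRF and actin genes stood out. A fold change given for a list member is that of 1 region, with the smallest adjusted p within 50 kb of its TSS. It does not describe the gene as a whole. Of 454 regions within 50 kb of 22 YAP/TAZ targets, 190 (41.9%) rose at 50 kPa, against 17.6% of other regions near protein-coding genes (Fisher's exact test, adjusted p = 4.36e-32). Against random gene lists matched on regions per gene, adjusted p was 0.00127, which rests on the smallest p they can give. For 19 of these genes more regions rose than fell, and for 3 more fell. In all, 195 regions rose when adjusted over the list alone. In the authors' deposited table, the log2 fold change was 2.01 at ANKRD1, a stretch-responsive ankyrin repeat gene, and 2.89 at CCDC80, which encodes a matrix protein. AMOTL2, an angiomotin gene, had a region with 323 ± 32.6 tags at 1 kPa and 1518 ± 186 at 50 kPa. Of 592 regions near 24 MRTF/SRF and actin genes, 205 (34.6%) rose (Fisher's exact test, adjusted p = 2.76e-22; matched lists, adjusted p = 0.00127). Here 21 genes had more risen than fallen regions and 2 the reverse, with 210 regions risen when adjusted over the list alone. LIMA1, which encodes an actin-bundling LIM protein, had 1.97 in the authors' deposited table, FHL2 1.64, TAGLN2 1.78 and PDLIM7 2.15. The median log2 fold change was 0.35 for the YAP/TAZ list and 0.28 for the MRTF/SRF list, and stayed positive when tags were scaled to library totals (0.13 and 0.06) or to tags in regions (0.26 and 0.19). The 9 genes named by the study had 66 of 161 regions risen (41.0%; 71 adjusted over the list alone; Fisher's exact test, adjusted p = 2.72e-11; matched lists, adjusted p = 0.00127). These 9 genes were picked by the study on its own data, so their excess is not independent evidence. The YAP/TAZ list shares 2 of them and the MRTF/SRF list 1.

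Other lists were mixed. Among 535 regions near 25 matrix and fibrosis genes, 137 rose and 120 fell. POSTN, which encodes periostin, had a log2 fold change of 3.11 in the authors' deposited table. COL1A1, which encodes a type I collagen chain, was at −1.78 in the authors' deposited table. Fisher's exact test called the excess in both directions (adjusted p = 1.78e-05 and 0.000346), but against matched lists adjusted p was 0.195 and 0.251. Adjusted over the list alone, 142 rose and 127 fell. Of 274 regions near AP-1 and immediate early genes, 69 rose and 61 fell (77 and 67 adjusted over the list alone; adjusted p = 0.00593 and 0.0116 by Fisher's exact test, 0.384 and 0.404 against matched lists). IER3 was at 1.74, JUN at 2.60 and FOSL2 at −2.03 in the authors' deposited table. Focal adhesion and integrin genes had 115 of 489 regions risen. In the authors' deposited table, regions of ACTN4 and PTK2, which encodes focal adhesion kinase, were at 1.68 and 1.61, and one of ITGB3, an integrin subunit gene, at −1.95. Cell cycle genes had 80 of 328 risen and 51 fallen (CCNA2, 1.59, and MCM5, −2.19, in the authors' deposited table), and the BCL2 family 50 of 206 (BCL2L1, 2.27, and MCL1, 1.95, in the authors' deposited table). By Fisher's exact test these 3 lists had adjusted p of 0.00395, 0.00603 and 0.0402, and against matched lists 0.384, 0.177 and 0.289. In these lists 122, 84 and 52 regions rose when adjusted over the list alone. Closer to the TSS the cell cycle list rose more clearly, with 39 of 75 regions within 10 kb (17 genes with more risen than fallen regions and 3 the reverse; Fisher's exact test, adjusted p = 6.16e-10). The BCL2 family had no excess within 10 kb, with 7 of 46 regions risen (15.2%, against 18.7% of other regions). By Fisher's exact test its adjusted p was 0.870, and 5 genes had more risen and 2 more fallen regions. No matched lists were run at that distance. Fibroblast markers had 52 of 225 regions fallen (54 when adjusted over the list alone; adjusted p = 0.0116 by Fisher's exact test and 0.404 against matched lists). In the authors' deposited table, TWIST2 was at −3.12, DCN at −2.49 and THY1 at 1.01. No excess of risen regions was called for nuclear envelope genes (53 of 238, 0.155), inflammatory and NF-kB genes (59 of 280, 0.234), sterol and lipid genes (24 of 171, 0.348) or the Wnt pathway (55 of 266, 0.301), all by Fisher's exact test. Adjusted over the list alone, 53, 59, 24 and 56 rose. The same held for markers of epithelial cells (39 of 189 regions), keratinocytes and melanocytes (15 of 70), endothelium (17 of 131), immune cells (16 of 72) and neurons (14 of 52). Their adjusted p ran from 0.187 to 0.456 by Fisher's exact test, with 39, 15, 17, 16 and 14 regions adjusted over the list alone. Single regions near members of these lists rose all the same. Those named lay near LMNB2, a lamin gene, LIF, a cytokine gene, SREBF2 and DKK1, which encodes a secreted Wnt antagonist. Their log2 fold changes were 2.57, 2.74, 1.66 and 2.51 in the authors' deposited table. Of 12 nuclear envelope genes, however, 12 had a risen and 8 a fallen region, and of 18 inflammatory genes 17 and 16.

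**Figure D2:**
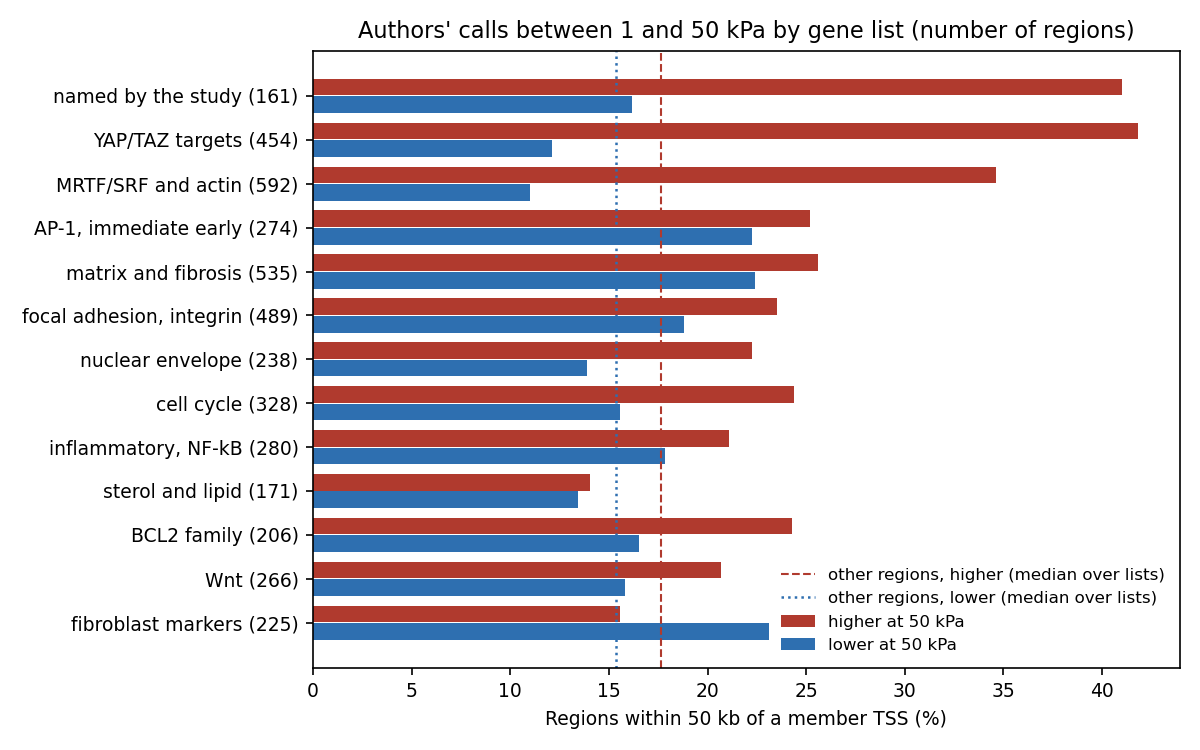
Percent of the regions within 50 kb of a member's TSS that were more accessible (red) or less accessible (blue) at 50 kPa than at 1 kPa in the authors' calls, for 13 gene lists with the number of regions in brackets; the dashed and dotted lines give the shares of the other regions near protein-coding genes. YAP/TAZ targets (41.9%) and MRTF/SRF and actin genes (34.6%) have the highest red bars beside the genes named by the study (41.0%), and fibroblast markers have the highest blue bar (23.1%).

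The balance of both directions depended on the scaling. With limma-voom on tags recovered from the tables, 46329 regions were higher and 44214 lower at 50 kPa, and with tags scaled to library totals 31010 were higher and 61054 lower. That scaling moved all log2 fold changes by −0.22, and scaling to tags in regions moved them by −0.0879. The share of tags in the regions was 73.4% to 74.1% at 1 kPa and 68.7% to 69.4% at 50 kPa.

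The peak lists allowed the same comparison over more fibroblast libraries. Regions that held 1 of the 50000 strongest peaks in all 9 untreated or DMSO libraries at 50 kPa and in 0 of 8 at 1 kPa were led by regions near DPYD, which encodes an enzyme of pyrimidine breakdown (chromosome 1, 97999077 to 97999938), and ARHGAP21, which encodes a GTPase-activating protein (chromosome 10, 24762898 to 24763507). Next came DLC1, which encodes another such protein (chromosome 8, 13108369 to 13109428). Those with peaks in all 8 libraries at 1 kPa and in 0 of 9 at 50 kPa were led by regions near FGD2, an exchange factor gene for CDC42 (chromosome 6, 37083279 to 37084078), PKDCC, TCF7L1, which encodes a TCF/LEF transcription factor (chromosome 2, 85215296 to 85216420), and RGS3. Further 50 kPa regions among the leading 10 lay near BPTF, BECN1, TRPM1, SEC62, NDST1, RGS4 and CERT1, and further 1 kPa regions near DRC10, ARHGEF3, YPEL2, STC2, USP3 and MPHOSPH6. In all, 3062 of 41463 tested regions held peaks more often at 50 kPa and 2850 more often at 1 kPa (exact conditional test stratified by set, two-sided, adjusted p of 0.05; the 20 leading regions had adjusted p = 0.00909). Of these, 95.5% and 94.2% overlapped a region that the authors' deposited table called in the same direction, and 3 and 3 regions one called in the opposite direction, with BDC4 libraries in both. Without any one set the exact test called 0 regions in either direction, with a smallest possible p of 0.005 in place of 0.00025. Without BDC3, BDC4 and the DMSO libraries, 5689, 5336 and 6463 regions then had an unadjusted p under 0.05, against 11210 with all. Leaving out 1 BDC3 library, or replicate 1 or 2 of BDC4 at 50 kPa, left 1633 to 2024 regions more often open at 50 kPa and 1054 (without BDC3 at 1 kPa, replicate 1) to 2064 at 1 kPa.

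A stiffness index gave 1 value per library: the percent of the 39495 regions more accessible at 50 kPa that held 1 of its 50000 strongest peaks, minus the same percent for the 38652 regions more accessible at 1 kPa. The inhibitor-set libraries had no part in choosing these regions, but libraries matched to BDC4 at 1 and 50 kPa did. In DMSO-treated fibroblasts the index was −4.09 ± 0.953 (SD, n = 3) at 1 kPa and 27.9 ± 0.167 (SD, n = 3) at 50 kPa, a difference of 32.0 percentage points (SE 0.559). Peaks covered 31.6% of the 50 kPa regions at 1 kPa and 47.0% at 50 kPa, and 35.7% and 19.1% of the 1 kPa regions. Among single regions, those of MYH9, NF2, RANGAP1, SKP2 and SUDS3 held a peak in 0 of 3 DMSO libraries at 1 kPa and 3 of 3 at 50 kPa, and that of RASL12 in 3 of 3 and 0 of 3. Those of FZD2, RFLNB and BMF held one in 3 of 3 on both gels, so peak presence did not show the lower accessibility of BMF on the stiff gel. The regions at CCN1 and CCN2 held none of the 50000 strongest peaks in any DMSO library. With 3 against 3 libraries the exact permutation test cannot go below p = 0.1 (two-sided). This difference reached it (adjusted p = 0.15 over 9 contrasts). Permuted within inhibitor over the DMSO, CCG-222740 and verteporfin libraries, the stratified difference was 33.6 points (exact permutation test, p = 0.00025, the smallest that 4000 arrangements can give). In all, 9004 regions had a peak in every DMSO library of one stiffness and none of the other, against at most 190 for other splits of these libraries. The leading ones lay near SUDS3, ABI3BP, BDH1, DLC1 and TRPM1 at 50 kPa and near FGD2, CCDC185, ELOF1, DRC10 and N4BP1 at 1 kPa. The index differed by 24.2 points in BDC3, with 3.91 ± 2.91 (SD, n = 2) at 1 kPa. It differed by 31.8 points in BDC4, with −5.39 ± 0.158 (SD, n = 3) at 1 kPa, but there the choice of regions favours a difference. Libraries on 1 gel shared more of their peaks with each other (Jaccard index 0.775 in the DMSO arm) than with those on the other gel (0.626).

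**Figure D3:**
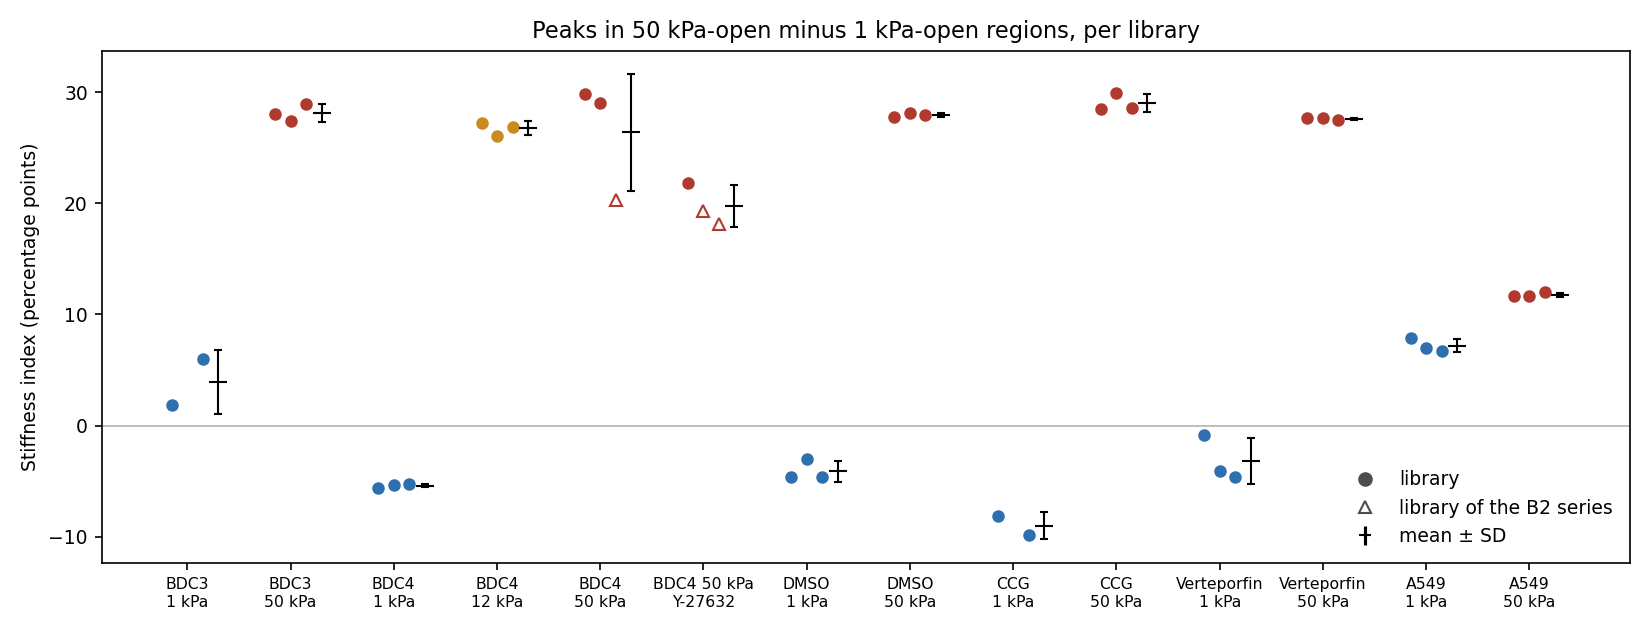
Stiffness index in percentage points for each of the 40 libraries, by set, treatment and stiffness (blue 1 kPa, yellow 12 kPa, red 50 kPa); open triangles mark B2 libraries, and black bars give the mean ± SD of each group. Without Y-27632, fibroblast group means lie between 26.4 and 29.0 at 50 kPa and between −9.01 and 3.91 at 1 kPa, A549 means are 7.20 and 11.8, and the B2 library at 50 kPa without inhibitor (20.3) lies beside the Y-27632 libraries.

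The arm at 12 kPa placed an intermediate stiffness beside the soft and the stiff gel. Fibroblasts at 12 kPa had an index of 26.7 ± 0.615 (SD, n = 3), close to the 26.4 ± 5.25 (SD, n = 3) at 50 kPa. The 12 kPa libraries (26.1 to 27.3) lay below the BDC4 libraries at 50 kPa outside B2 (29.8 and 29.0) and above the B2 library (20.3). Regions of MYH9, NF2, SKP2 and RAD18, with a peak in all DMSO libraries at 50 kPa and none at 1 kPa, held one in 3 of 3 libraries at 12 kPa, and that of RANGAP1 in 2 of 3. Those of MMP14, TSPAN11 and CAPS, with the reverse pattern under DMSO, held one in 0 of 3, but those of RASL12 and COPS8 in 2 of 3. Regions of FZD2, ANKRD1, PRCD and BMF held a peak in all DMSO libraries on both gels, and at 12 kPa in 3 of 3 for the first 3 and 0 of 3 for BMF. The index was 32.1 points (SE 0.367) above that at 1 kPa. Because the 1 kPa libraries took part in choosing the regions, this distance is not an independent test. Its difference from 50 kPa was 0.370 points (SE 3.05; exact permutation test, p = 1). Without the B2 library at 50 kPa it was −2.65 points, and with all deposited peaks −1.36, so its sign was not stable. Libraries at 50 kPa also took part in choosing the regions, so this difference is not an independent test either.

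Y-27632 was added to fibroblasts on the stiff gel to ask which of these regions depend on ROCK activity. With Y-27632 for 1 h, regions at CCN1, CCN2, ACTG1 and SKP2 were less accessible, and regions near RHOB and in ITGA2 more accessible. Of the 3 libraries with Y-27632, 2 are of the B2 series, against at most 1 of the 2 in the table without it. The calls, tags and gene lists below therefore do not separate the inhibitor from the library series. At CCN1 tags were 973 ± 8.67 (SD, n = 2) without and 384 ± 34.4 (SD, n = 3) with the inhibitor, and at CCN2 192 ± 44.5 and 21.8 ± 5.16. An intergenic region near ACTG1, which encodes a cytoplasmic actin (chromosome 17, 81507133 to 81509559), went from 2448 ± 451 to 907 ± 129 tags. A region near COL8A1, which encodes a collagen chain (chromosome 3, 99562886 to 99563787), went from 385 ± 9.79 to 88.6 ± 3.50 tags. The 3' UTR of THBS1, which encodes the matrix glycoprotein thrombospondin-1 (chromosome 15, 39597550 to 39599780), was less accessible with Y-27632, while its log2 fold change between 50 and 1 kPa was −0.30 (adjusted p = 0.107) in the authors' deposited table. An intergenic region near RHOB, which encodes a small GTPase (chromosome 2, 20424523 to 20425984), went from 594 ± 35.4 to 1001 ± 134 tags. An intronic region near ITGA2, which encodes a collagen-binding integrin subunit (chromosome 5, 53004699 to 53005447), went from 333 ± 38.0 to 589 ± 72.8. Of all regions, 5324 were more accessible without the inhibitor and 1801 more accessible with it in the authors' deposited table. The authors' deposited table gave log2 fold changes (50 kPa over 50 kPa with Y-27632) of 3.14 for CCN2, 2.11 for COL8A1, 1.42 for ACTG1, 1.33 for CCN1 and 1.30 for THBS1, and −0.77 for RHOB, −0.84 for ITGA2 and −1.62 for SLC20A1, a phosphate transporter gene. Of the 9 genes the study names, 8 had an adjusted p under 0.05 in the authors' deposited table at the same region, and RFLNB had 0.18. Other leading regions lay near RAD18, PPP2R3A, KCNJ6 and TSEN15 (lower with Y-27632) and near RCN1, NT5E, MESP2, IFNE, WDR76, EPAS1 and ADAM28 (higher).

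YAP/TAZ targets had 55 of 454 regions (12.1%) more accessible without Y-27632, against 2.01% of other regions (Fisher's exact test, adjusted p = 1.77e-24; matched lists, adjusted p = 0.00127). More regions were lower than higher with the inhibitor for 14 genes and the reverse for 3, and 71 regions were lower when adjusted over the list alone. MRTF/SRF and actin genes had 34 of 592 (5.74%; 38 adjusted over the list alone; adjusted p = 5.53e-07 by Fisher's exact test, 0.0181 against matched lists), among them regions of MYL9, a myosin light chain gene, LIMA1 and TPM1, a tropomyosin gene. MYL9 and LIMA1 had log2 fold changes of 1.16 and 1.04 in the authors' deposited table. Matrix and fibrosis genes had 39 of 535 (7.29%; 41 adjusted over the list alone; adjusted p = 1.05e-10 by Fisher's exact test, 0.00127 against matched lists), led by THBS1, POSTN and LOXL2. The list's median log2 fold change was −0.02, of the opposite sign to these calls, though above that of 87.6% of the matched random lists. The medians of the YAP/TAZ and MRTF/SRF lists were 0.13 and 0.05, and that of the MRTF/SRF list turned to −0.03 when tags were scaled to those in regions. In the other direction, focal adhesion and integrin genes had 22 of 489 regions (4.50%, against 0.854%) more accessible with Y-27632 (23 adjusted over the list alone; adjusted p = 1.21e-08 by Fisher's exact test, 0.0038 against matched lists). Another 12 regions of this list were lower with Y-27632, and genes were split, 6 with more higher and 5 with more lower regions. ITGA3 was at −0.57 and ITGB5 at −0.88 in the authors' deposited table, but ACTN4 at 1.025. AP-1 genes had 8 of 274, with 4 lower (8 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0281; matched lists, adjusted p = 0.640), with FOSB at −0.86 and JUNB at −0.80 in the authors' deposited table. The study's 9 genes had 24 of 161 regions (27 adjusted over the list alone; adjusted p = 4.14e-13 by Fisher's exact test), which is not independent evidence. With limma-voom on the recovered tags 13651 regions were higher without and 5875 higher with Y-27632, and scaled to tags in regions 10110 and 9031.

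Both tables share their 50 kPa libraries. Of the 5324 regions lower with Y-27632, 5100 (95.8%) were also more accessible at 50 than at 1 kPa, where independent lists would share 937. Of the 1801 regions higher with it 1167 (64.8%) were less accessible at 50 kPa, against 310. Regions called in opposing directions numbered 83 and 18, against 317 and 917. The fold changes of both comparisons had a correlation of 0.615 across 187858 regions, against 0.630 simulated with no effect, and a covariance of 0.280 against 0.0568 simulated. With a separate 50 kPa library in each comparison the correlation was 0.389 or 0.467. Sharing libraries can by itself raise the overlap of calls above that of independent lists, and this overlap was not simulated. How much of it comes from the shared libraries is therefore unknown. Regions are not independent replicates.

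Over the peak lists, the index was 26.4 ± 5.25 (SD, n = 3) at 50 kPa without and 19.7 ± 1.87 (SD, n = 3) with Y-27632, a difference of −6.64 points (SE 3.22; exact permutation test, p = 0.2; adjusted p = 0.257). The test did not set this difference apart from the spread between replicates. Within the BDC4 series it was 29.4 (n = 2) without and 21.8 (n = 1) with the inhibitor, a difference of −7.61. Within B2 it was 20.3 (n = 1) and 18.7 (n = 2), a difference of −1.63. The untreated B2 library thus lay with the treated ones, and the names of the table's columns do not tell which of its libraries belong to B2. Regions with a peak in every library of 1 group and none of the other lay near CXCL5, IQSEC1, CPM, CAMKK2 and RASSF2 with Y-27632 (319 regions) and near COL8A1, STX6, RLN2, OR5B17 and GSK3B without it (410). The split of B2 against the other libraries gave more such regions, 1251 against 729 in both directions.

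CCG-222740 and verteporfin were tested for their effect on chromatin at each stiffness. Fibroblasts under either compound differed between the soft and stiff gels. Regions of MYH9, NF2, SKP2, RAD18 and PDLIM7 held a peak in 3 of 3 libraries at 50 kPa and in at most 1 at 1 kPa with either compound. Those of RASL12, TSPAN11 and CAPS held one in every library at 1 kPa and in none at 50 kPa. With CCG-222740 the index was −9.01 ± 1.23 (SD, n = 2) at 1 kPa and 29.0 ± 0.794 (SD, n = 3) at 50 kPa, a difference of 38.0 points. With verteporfin it was −3.17 ± 2.04 (SD, n = 3) and 27.6 ± 0.0824 (SD, n = 3), a difference of 30.8 points. Against the DMSO step, that with CCG-222740 was 5.97 points wider (SE 1.13; permutation test, p = 0.005, compound labels permuted within each gel), and that with verteporfin 1.26 points narrower (SE 1.31; permutation test, p = 0.405). Over peaks with −log10 q of at least 5 the verteporfin step was narrower still, with a permutation p under 0.05. The other alternatives stayed above that threshold. CCG-222740 differed from DMSO by 1.06 points (SE 0.469; exact permutation test, p = 0.1) at 50 kPa and by −4.91 points (SE 1.03; exact permutation test, p = 0.1) at 1 kPa, both with adjusted p = 0.15. Verteporfin differed by −0.339 points (SE 0.108; exact permutation test, p = 0.1, adjusted p = 0.15) at 50 kPa and by 0.919 points (SE 1.30; exact permutation test, p = 0.5, adjusted p = 0.562) at 1 kPa, where leaving out verteporfin replicate 1 turned the sign (−0.249). The smallest p of each of these contrasts is 0.1. The effects of the compounds were not tested against each other, and their doses differ.

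At 50 kPa, 369 regions had a peak in all CCG-222740 libraries and in no DMSO library, near SEPTIN7, UCKL1, FTL, which encodes ferritin light chain, CLUH and PLEKHF1. The reverse held for 505, near VAC14, CDC42EP4, an effector gene of CDC42, LINC02953, COMMD7 and RFPL4B. For verteporfin these numbers were 243 (near NIPSNAP2, PTK2, DCLK2, SMIM24 and AHI1) and 258 (near SEPTIN9, C1GALT1, SOBP, PLCB1 and GPR26) at 50 kPa. At 1 kPa they were 201 (near CAMK2N1, FCRL5, SUSD6, TSC22D2 and ACSS2) and 309 (near MAB21L4, COMP, LRPAP1, RAP2B and MTHFS). YAP/TAZ targets had 1 and 1 of the CCG-222740 regions, 0 and 0 of the verteporfin regions at 50 kPa, and 3 and 0 of those at 1 kPa. MRTF/SRF and actin genes had 2 and 4, 1 and 1, and 0 and 1. With all deposited peaks the numbers were 64 and 3432 for CCG-222740, and for verteporfin 181 and 865 at 50 kPa and 202 and 1457 at 1 kPa. The balance of both directions thus depended on the peaks taken. These are counts with no test per region.

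A549 placed the same pair of gels under an epithelial cancer line. On 50 kPa, A549 gained peaks near NOTCH1, which encodes a signalling receptor (chromosome 9, 136572010 to 136572771), CEP89, TM2D3, C1orf116 and IFFO2. On 1 kPa they gained peaks near ARHGEF2, which encodes a microtubule-bound exchange factor (chromosome 1, 155983301 to 155984131), LHFPL2, ANK1, LINC03040 and PIK3IP1. Regions with a peak in 3 of 3 libraries on one gel and 0 of 3 on the other numbered 3094 at 50 kPa and 1970 at 1 kPa, against at most 212 in both directions for other splits of the 6 libraries. They included 12 regions near MRTF/SRF and actin genes at 50 kPa and 2 at 1 kPa, 11 and 3 near YAP/TAZ targets, 13 and 4 near inflammatory genes, 10 and 4 near focal adhesion genes and 8 and 1 near matrix genes. Epithelial markers had 7 and 2, and the Wnt pathway and the genes named by the study 6 and 1 each. Counts were 7 and 4 for the BCL2 family, 5 and 3 for cell cycle genes, 3 and 2 for AP-1 genes and 0 and 2 for neuronal markers. These are counts without a test. The MYH9 region held a peak in 1 of 3 A549 libraries at 1 kPa and 3 of 3 at 50 kPa, and that of NF2 in 0 and 3, whereas those of SKP2 and SUDS3 held none. The index was 7.20 ± 0.609 (SD, n = 3) at 1 kPa and 11.8 ± 0.199 (SD, n = 3) at 50 kPa, a difference of 4.57 points (SE 0.370; exact permutation test, p = 0.1, the smallest possible; adjusted p = 0.15). The difference in DMSO-treated fibroblasts was 27.5 points larger (SE 0.670; cell type labels permuted within each gel, permutation test, p = 0.005, the smallest that 400 arrangements can give). The index regions were chosen by their change in fibroblasts, which favours a larger step there. Only 49.0% of the 50 kPa regions and 42.0% of the 1 kPa regions held any A549 peak. The larger step therefore does not show a weaker response of A549.

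Markers of other cell types were read at promoters to describe the cells. Peaks lay at 78.8% to 97.0% of fibroblast marker promoters in the inhibitor set and at 45.5% to 48.5% in A549. In BDC4 the share was 42.4% ± 5.25 (SD, n = 3) at 1 kPa and 63.6% ± 15.8 (SD, n = 3) at 50 kPa. In BDC3 it was 59.1% ± 19.3 (SD, n = 2) and 72.7% ± 24.1 (SD, n = 3). Epithelial marker promoters held peaks at 16.7% to 25.0% in fibroblasts and at 44.4% and 50.0% in A549. Endothelial marker promoters held none in any fibroblast group and 12.5% and 4.17% in A549. Peaks lay at keratinocyte and melanocyte promoters in 20.8% to 25.0% in fibroblasts and 29.2% and 33.3% in A549, at immune promoters in up to 14.3% and at neuronal promoters in 23.8% to 52.4%. In BDC4 at 1 kPa the neuronal share (47.6%) was above the fibroblast share (42.4%), so these markers do not identify the cells there. In the other fibroblast groups the fibroblast share was the higher of both. Fibroblast and A549 libraries shared fewer peaks (Jaccard index 0.359) than libraries of BDC and the inhibitor set (0.591). For peaks per library, no contrast of the index family gave a p under 0.2 in exact permutation tests, with 126707 ± 10202 (SD, n = 3) for DMSO at 50 kPa and 103251 ± 21757 (SD, n = 3) for CCG-222740 at 50 kPa.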

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

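The tests of differences between 2 arms, the percent shares of the B2 library and of regions open in A549, and the test leaving out single CCG-222740 or DMSO libraries were chosen only after the patterns were seen; for the last of these its result was also known.

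The step of the stiffness index from 1 to 50 kPa was 27.46 points larger in DMSO-treated fibroblasts than in A549 (SE 0.670; cell type labels permuted within each gel, permutation test, p = 0.005, the smallest that 400 arrangements can give). The p was 0.005 too with each cell type centred on its mean over both gels, so a constant difference between the cell types does not give it. Regions closed in A549 cannot gain or lose a peak there, and of the 39495 and 38652 regions of the index 49.0% and 42.0% had a peak in any A549 library. Over these regions alone the A549 step was 9.57 points and the fibroblast step 35.3, so A549 kept 27.15% of it, against 14.3% over all regions. Missing regions may thus account for part of the gap, but how much cannot be told from this share. A region was kept if it had a peak in any A549 library, while the index counts only the strongest peaks of each library. Regions weakly open in A549 may therefore still add little to its step. The regions were also chosen in fibroblasts, so that a weaker response of A549 and a response at other regions cannot be told apart. Differences in culture or tissue of origin were not tested.

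CCG-222740 moved the index up by 1.06 points at 50 kPa and by −4.91 points at 1 kPa against DMSO, which made the step between both gels 5.971 points wider (SE 1.13; compound labels permuted within each gel, permutation test, p = 0.005, the smallest that 200 arrangements can give). At 50 kPa CCG-222740 replicate 2 (29.9) lay further from DMSO (27.8 to 28.1) than replicates 1 (28.5) and 3 (28.6), so it raised the shift there. Every CCG-222740 library lay above every DMSO library at 50 kPa and below every one at 1 kPa. The opposite directions thus did not rest on 1 library. Leaving out any library of the 4 groups in turn therefore had to keep them (0 omissions lost them) and is no further evidence. The CCG-222740 libraries at 50 kPa had 103251 ± 21757 peaks (SD, n = 3), so depth may differ. Over the 25000 strongest peaks 57.44% of the widening was kept (SE 9.815), but so was 52.28% of the DMSO step, since fewer peaks shrink every index difference. The kept share therefore says nothing about depth, which stays open beside widening by the compound itself. The SE and the DMSO step were added to this comparison and to that for Y-27632 after the values were seen.

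The index fell by 6.64 points with Y-27632 at 50 kPa in the pooled libraries, a difference with an exact permutation p of 0.2, and 2 of the 3 treated libraries belong to the B2 series. A position on the way from untreated to treated was taken over the regions that the authors' deposited table calls for Y-27632. Its start was the mean of the 2 other untreated BDC4 libraries at 50 kPa, and its end the mean of the 3 treated ones. The untreated B2 library lay 76.91% of this way. The libraries at 12 kPa, and those of BDC3 and DMSO at 50 kPa, lay at 8.31% to 19.1%. A difference between library series therefore may account for much of the lower index, and a wrong label of that library would look alike. Depth stays open, since the 58.39% of the difference (SE 26.5) kept over the 25000 strongest peaks is near the 52.28% that the DMSO step kept. Within each series, however, the treated libraries lay further along than the untreated ones: 78.83% for the 1 treated library outside B2, and 106.9% and 114.3% for the 2 treated B2 libraries. These regions were called with the treated libraries, so this is not an independent test. It leaves an effect of Y-27632 open, as do the index differences of −7.61 points outside B2 and −1.63 within it.

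Other splits of the libraries were run for each count of regions. The presence test called 5912 regions, and of 100 splits within sets 1, the real one, gave that many. The highest of the others was 0. A random split of these libraries would thus rarely give as many calls. Splits of libraries cannot, however, tell stiffness from a difference between cultures if the replicates on a gel share a culture. With 3 against 3 libraries the 10 splits cannot give a share under 0.05: the real split was the highest (1 of 10) for A549 (5064 regions, next 212), BDC4 (6924, next 314), DMSO (9004, next 190), CCG-222740 at 50 kPa (874, next 385), verteporfin at 50 kPa (501, next 344) and verteporfin at 1 kPa (510, next 398). For verteporfin this did not hold with all peaks, where other splits reached 2236 against 1046 at 50 kPa and 1999 against 1659 at 1 kPa, or at −log10 q of 5 (2475 against 840 and 2305 against 1687). For Y-27632, 2 of 10 splits gave as many as the real 729; the highest, with 1251, set the 3 B2 libraries against the others.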

How the results depend on the processing

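The limma fits, the list comparison with matched random lists, the differences of differences and the version without B2 libraries were added after the data were seen; the cause of the changes below was not tested unless given. The depth of the libraries outside the tables is unknown, so alternatives that use weaker peaks move with it. The planned count test was not run, since the tables hold log2 values with the authors' own comparison. Tags were recovered from these values later, and of count methods only limma-voom was run on them. The motif comparison, which needs a genome, was not run either. The planned longer overlap of region and peak moved nothing, since each peak lies within its merged region. An added version, with the peak over at least 1/2 of the region, gave 2731 and 2629 presence calls and, for CCG-222740 at 50 kPa, 324 regions in its libraries alone and 854 in DMSO alone. Among alternatives, 83 of 108 values of the 9 index contrasts moved by less than 1 SD (5 of the 108 took the other sign), as did 85 of 86 for peaks per library (10 took the other sign); all 9 for similarity moved by at most 0.05 (1 took the other sign). Differences of differences kept their side of the threshold in 52 of 53. Within 1.5 times stayed 27 of 54 presence counts, 31 of 34 stiffness table counts, 5 of 34 Y-27632 table counts, 16 of 35 counts of regions in all or none and 7 of 12 counts of called lists; of single gene lists 198 of 228 kept their side of the threshold, with 24 weaker, 5 stronger and 1 reversed.

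Stiffness calls in the tables numbered 23263 higher and 25612 lower at a log2 change of at least 1, and 61054 lower by limma-voom with header totals. For Y-27632, regions higher without and with the inhibitor numbered 3094 and 584 at adjusted p of 0.01 and 1494 and 555 at a log2 change of at least 1. They numbered 13651 and 5875 by limma-voom, 13756 and 5346 without a filter, 12191 and 4612 scaled to header totals, 10110 and 9031 scaled to tags in regions, and 8411 and 4276 by limma on transformed values. Leaving out 1 column gave 6678 (without 50 kPa column 2) to 22176 (without Y-27632 column 1), and 1111 (without 50 kPa column 1) to 16063 (without Y-27632 column 1); a lone sample was taken to vary like the other groups.

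Presence calls at 50 kPa numbered 1425 with all peaks, 1377 with the 25000 strongest, 1310 at −log10 q of 5 and 7782 in 5 strata with the inhibitor libraries. At 1 kPa they numbered 1363 with the 25000 strongest and 8346 in 5 strata. Leaving out a set gave 0 and 0 by the exact test, and 1 library 1633 (without BDC3 1 kPa replicate 1) to 2498 and 1054 (the same) to 2238.

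Index differences with all peaks, the 25000 strongest and −log10 q of 5 were 48.9, 16.7 and 49.2 for DMSO and 6.74, 2.44 and 6.15 for A549. They were −6.36, −2.54 and −7.12 for CCG-222740 at 1 kPa, −0.00925, −0.104 and −0.188 for verteporfin at 50 kPa, and 55.7, 18.0 and 56.0 for 12 against 1 kPa. The difference was 1.88 with all peaks for CCG-222740 at 50 kPa, 3.04 at −log10 q of 5 for verteporfin at 1 kPa, and −11.8 (all) and −11.5 (q) for Y-27632. Regions at adjusted p of 0.01 gave 39.4 (DMSO), 5.48 (A549), −6.19 (CCG-222740 at 1 kPa) and 39.8 (12 kPa), and those with a log2 change of 1 gave 35.0 (DMSO) and 34.4 (12 kPa). The verteporfin difference of differences, −1.26 (permutation test, p = 0.405), was −3.23 at −log10 q of 5 (permutation test, p = 0.035); the other alternatives had p from 0.165 to 0.93.

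Regions in all of 1 group and none of the other, with all peaks and the 25000 strongest, numbered 7723 and 2824 (A549), 16483 and 3626 (BDC4) and 17802 and 4429 (DMSO). They numbered 3496 (64 with the compound and 3432 with DMSO) and 511 (CCG-222740), 1046 and 310 (verteporfin, 50 kPa), and 1979 and 423 (Y-27632), and 1659 with all peaks for verteporfin at 1 kPa. At −log10 q of 5 they numbered 15995 (BDC4), 15668 (DMSO), 4181 (CCG-222740; 19 and 4162), 840 and 1687 (verteporfin, 50 and 1 kPa) and 1958 (Y-27632).

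Of 8 gene lists called for regions higher at 50 kPa, 3 were called against matched lists; for lower regions 0 were called within 10 kb (Fisher's exact test, 2 at unadjusted p under 0.05) or against matched lists (2 at unadjusted p under 0.05), and for regions higher with Y-27632 1 by nearest TSS and 1 against matched lists. The BCL2 family odds ratio for higher regions turned from 1.498 to 0.7783 within 10 kb (adjusted p = 0.870).

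Replicate numbers were not taken to pair the samples: same-number table columns had correlations of deviations from −0.0252 to 0.00101. In a check of peak presence added after the data were seen, same-number libraries had −0.0269 to 0.0197 in the inhibitor set, −0.00314 to 0.00446 in A549, −0.0488 to 0.0785 in BDC3 and −0.00168 to 0.0142 in BDC4 without B2. With the replicate block limma-voom called 44832 and 42363 regions for stiffness and 9498 and 4044 for Y-27632, and the presence test 0 and 0, with 4273 regions at unadjusted p under 0.05, since the block allows no p under 0.0156.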

Other observations

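The overlaps of peak regions with the authors' stiffness calls were added after the data were seen.

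Of the 3094 regions with a peak in all A549 libraries at 50 kPa and none at 1 kPa, 34.6% overlapped a region that the authors' deposited table calls higher at 50 kPa in fibroblasts, and 9.86% one called lower. For the 1970 regions of the soft gel these shares were 5.79% and 17.9%. The regions near NF2 and EMD, which encodes the inner nuclear membrane protein emerin, held a peak in 0 of 3 A549 libraries at 1 kPa and 3 of 3 at 50 kPa, as did one at −2492 bp from the TSS of BCL2L1 along the chromosome, annotated to the promoter of another transcript. Regions found in Y-27632 libraries alone overlapped calls lower at 50 kPa in 34.2% of cases and calls higher at 50 kPa in 9.40%, and those found in untreated libraries alone overlapped higher calls in 72.7% and lower calls in 3.90%. The untreated libraries are matched to the 50 kPa columns behind these calls, so the agreement for Y-27632 is not independent. For CCG-222740 at 50 kPa the shares of higher and lower calls were 39.3% and 16.8%, and for regions in DMSO alone 26.1% and 22.4%. For verteporfin at 50 kPa they were 24.7% and 23.1%, and for DMSO alone 34.5% and 23.6%. Of all 224389 regions, 39495 were called higher and 38652 lower. The shares among all peak regions of a contrast were not taken, so the background of these overlaps is unknown.

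Single genes of lists for other cell types also had regions with calls in fibroblasts. In the authors' deposited table, an intronic region of PTPRC, the pan-leukocyte gene for CD45 (chromosome 1, 198671751 to 198672651), had a log2 fold change of 3.10 (50 over 1 kPa). Its tags were 106 ± 16.8 (SD, n = 3) at 1 kPa, 894 ± 87.0 (SD, n = 2) at 50 kPa and 421 ± 81.7 (SD, n = 3) with Y-27632. Regions near the keratin genes KRT7 and KRT19 were at 1.63 and 1.35 in the authors' deposited table, and those near TIE1, an endothelial receptor gene, and TP63, a regulator of stratified epithelia, at −2.57 and −2.60. In the nuclear envelope list, for which no excess of higher regions was called, a region of LMNB1 was at 1.26 and one of LBR at 1.73 in the authors' deposited table. IL11, a cytokine gene, and IDI1, an enzyme gene of isoprenoid synthesis, were at 2.60 and 2.81 in the authors' deposited table.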
